A study of Mus musculus with 18 samples.

How the data were processed

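Per the file headers, the deposited non-normalized tables hold 1 average signal intensity and 1 detection p-value for each probe on each of the 18 arrays. Per the labels, 550 ng of total RNA was amplified to biotinylated cRNA for each array. The submitters' processing notes name GenomeStudio 2009.2 and R 2.4.1. The authors' normalized matrix holds log2 values for 28721 probes, 24286 with values in liver and 17128 in fat, whose correlation with log2 of the deposited signal was at least 0.9996 in liver and 0.9999 in fat. It was normalized separately per tissue, with column medians of 7.88 to 7.89 in liver and 9.00 to 9.01 in fat, and the authors do not state the normalization method. The deposited detection p-values took 936 steps.

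The deposited signals, not the authors' log2 values, were used here, with R 4.3.3 and limma 3.58.1. Within each tissue the 9 arrays were background corrected, quantile normalized and turned to log2 with the neqc function of limma (offset 16), with the background estimated from the detection p-values. Probes with a detection p under 0.05 on all 3 arrays of at least 1 diet were kept, 16262 in liver and 19549 in fat, of which 13086 and 15274 had a gene name. Gene names come from GEO's annotation of the array platform, where 22883 probes have 1 gene, 13 have several and 5825 probes of the authors' matrix have none. Of the probes with 1 gene, 22836 have an Entrez identifier in the GRCm38.p6 annotation, which was used for names only. For each gene the probe with the highest mean over the arrays was kept, and probes without a gene name were counted but not analysed here. A linear model of limma was fitted to the 9 arrays of a tissue with empirical Bayes moderation, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The difference between tissues was fitted to all 18 arrays normalized together. Where a gene was undetected on all 3 arrays of a group, its values below the detection level of their array were raised to that level and the fold is given as at least the resulting ratio.

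The comparisons and 36 gene lists were chosen before the data were examined, as were the tests and alternatives apart from those named as later choices. Lists with at least 5 detected genes were tested with camera of limma at a preset correlation of 0.01, with the adjustment over the lists of a comparison. Lists with fewer were not tested, which left out B and plasma cell, cholangiocyte, skeletal muscle, epididymis and testis, and exocrine pancreas markers in liver, and drug-metabolising cytochromes P450, epididymis and testis, and exocrine pancreas markers in fat. Counts given over the list alone are adjusted by the Benjamini-Hochberg method over the genes of that list. The genes named are, by a rule, the 8 genes with the largest rise and the 8 with the largest decrease among those past the threshold whose arrays did not overlap, 4 each for LU against ND and for the tissue differences, and up to 4 members of each list described. For the tissue differences the rule leaves open which arrays must not overlap, and the reading was changed after values were seen, to no overlap in the tissue with the larger difference. Genes known only by a clone or LOC name were counted but not named.

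The method was tested on simulated data with 200 changed genes and 3 arrays per group. At 1.5-fold it recovered 74.6%, 77.6% and 68.7% of changed genes in liver for HFD against ND, LU against HFD and LU against ND, and 73.1%, 82.1% and 71.6% in fat. At 2-fold it recovered 91.0%, 91.0% and 95.5% in liver and 95.5%, 92.5% and 95.5% in fat, and at 4-fold at least 98.5% in each. For the tissue differences it recovered 65.7% and 47.8% at 1.5-fold, and 88.1% and 91.0% at 2-fold. Of simulated calls 4.24% to 8.72% were false. In 1 run per tissue only the raised list was called, too few for a false rate.

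Alternatives replaced 1 choice at a time: no background correction, cyclic loess or median scaling for quantile normalization, the authors' values, no detection filter or a stricter one (p under 0.01 on all arrays), all detected probes, moderation with trend and robust settings, only the 6 arrays of the diets compared, the replicate number as a block, and each array left out in turn. For lists, camera with an estimated correlation and fry were also run, where fry tests whether the genes of a set move one way and not whether they differ from other genes. Cyclic loess and median scaling for the lists and for the opposite-sign counts were added after seeing the data.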

Results

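Messenger RNA was measured on 18 Illumina mouse bead arrays, 9 from liver and 9 from epididymal adipose tissue, of male C57BL/6J mice (C56BL/6J in the strain field of the labels). Each tissue had 3 arrays from mice on a normal diet (ND), 3 from mice on a high-fat diet with 20% fat and 1% cholesterol (HFD) and 3 from mice on that high-fat diet with 0.005% (w/w) luteolin, a plant flavonoid (LU). The mice, 4 weeks old at arrival, ate these diets for 16 weeks, with 10, 13 and 13 mice in the ND, HFD and LU groups. The labels do not say that the arrays of a group came from separate animals with separate RNA, so the p-values measure only the spread between these samples, which may be technical. Between 15464 and 16998 probes per array were detected in liver and between 19113 and 19852 in fat. The median signal per array was 150 to 159.7 in liver and 194 to 216 in fat, and the number of arrays limits the precision. The tests covered 8937 genes in liver and 10240 genes in fat.

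In liver the first principal component, with 58.7% of the variance, placed the ND arrays between -27.3 and -25.3, the HFD arrays between 7.98 and 14.25 and the LU arrays between 14.2 and 19.6. In fat it held 60.8% of the variance, with ND arrays between -33.2 and -24.6, HFD arrays between 18.3 and 26.1 and LU arrays between 3.61 and 6.49. Within a group the lowest correlation between 2 arrays was 0.9935 in liver and 0.992 in fat. Below, gene and list values are log2 differences, for genes ± SE from limma with n = 3 arrays per group, and p-values are adjusted by the Benjamini-Hochberg method over the genes tested. For every named gene said to rise or fall within a tissue, the 3 arrays of 1 group lay above all 3 of the other, as for 40.9% to 54% of all genes (10% by chance). Other detected probes of a gene are given where 1 of them differed far less than the probe kept. Some values rest in part on background, with the gene detected on only 1 or 2 of the 3 arrays of the lower group: in liver Gpnmb, Sqle, Cyp2b23, Ms4a7, Trem2, Mmp13, Col1a1, Cyp2c55 and Ciart between HFD and ND, Pdgfrb between LU and HFD, and Gpnmb and Hspa1a between LU and ND. In fat these were Ccl2 and Pvalb between HFD and ND, Cpa3, Cma1, Tpsb2, Rbfox3 and Mmp3 between LU and HFD, and Cpa3 and Pon1 between LU and ND. A list of genes is said to have moved where the camera test of limma, with a preset correlation, passed, and adjusted p-values of lists are from that test. For lists that passed, a second adjusted p follows, from the same test with an estimated correlation. With an estimated correlation only 1 list kept its call, the triglyceride synthesis and lipid droplet list in liver with luteolin.

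The series concerns lipid metabolism and insulin resistance in diet-induced obesity, and the comparison of HFD with ND liver asks what the high-fat diet changed before luteolin is considered. HFD livers held more transcript of cytokine, macrophage and matrix genes than ND livers, and less of genes of sterol synthesis. Cidea, which enlarges lipid droplets and was not detected on the 3 ND arrays, was at least 35.1-fold higher (5.50 ± 0.22, adjusted p = 1.7e-06). Gpnmb, a glycoprotein of lipid-laden macrophages, rose (5.56 ± 0.24, adjusted p = 2.1e-06, other probe 0.96). Lcn2, the acute phase protein lipocalin 2, rose 13.4-fold (3.74 ± 0.25). Sqle, the squalene epoxidase of cholesterol synthesis, was lower (-2.79 ± 0.49, adjusted p = 0.0029). Cyp17a1, the 17-hydroxylase of steroid synthesis, was 7.04-fold lower (-2.82 ± 0.16). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, fell (-2.74 ± 0.58, other probe -0.96), as did the very long chain fatty acid elongase Elovl3 (-2.37 ± 0.22), Nipal1 (-2.20 ± 0.34), Fdps of the mevalonate pathway (-2.14 ± 0.40, other probe -0.83), the pyruvate dehydrogenase kinase Pdk4 (-2.10 ± 0.12) and Socs2, an inhibitor of growth hormone signalling (3.99-fold). The glutathione transferase Gsta1 (3.98 ± 0.23), Cyp2b9 (4.44 ± 0.55) and Cyp2b23 (3.90 ± 0.54) rose, Cyp2b13 was at least 8.32-fold higher and Cyp2b10 at least 7.76-fold higher. These belong to families of near-identical sequence whose probes can bind each other's transcripts, so the values do not settle which member rose. In all, 1599 genes rose and 1105 fell, of which 203 and 59 did so by more than 2-fold, and without HFD liver 2 only 695 were lower. With median scaling in place of quantile normalization the median difference of all genes was 0.115, with 2268 genes higher and 476 lower.

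Inflammatory and phagocyte genes rose as groups in HFD liver. Cytokines and chemokines had a median difference of 0.79 (adjusted p = 1.04e-08 and 0.223). Of 20 measured, 18 rose, 0 fell and 2 did not pass (the same over the list alone), among them the neutrophil attractant Cxcl1 (2.52 ± 0.22), Ccl4 (1.87 ± 0.14, other probe 0.38) and the receptor Tlr2 (1.18 ± 0.11). Macrophage markers had a median difference of 0.65 (adjusted p = 2.62e-07 and 0.246). Of 20 measured, 17 rose, 1 fell and 2 did not pass (18 higher and 1 lower over the list alone), with Ms4a7 (1.32 ± 0.19), lysozyme Lyz2 (1.31 ± 0.17) and the adaptor Tyrobp (0.94 ± 0.08) among those that rose. Lipid-associated macrophage markers had a median difference of 0.85 (adjusted p = 8.71e-06 and 0.223). Of 13 measured, 10 rose, 0 fell and 3 did not pass (the same over the list alone), including the lipid receptor Trem2 (2.20 ± 0.28), annexin Anxa2 (2.51 ± 0.23) and galectin 3, Lgals3 (1.86 ± 0.11). Kupffer cell markers, those of the resident liver macrophage, had 2 of 10 genes higher, 3 lower and 5 not passing (3 higher and 3 lower over the list alone, adjusted p = 0.921). Extracellular matrix genes had a median difference of 0.71 (adjusted p = 1.41e-06 and 0.246). Of 21 measured, 17 rose, 1 fell and 3 did not pass (the same over the list alone), with the collagenase Mmp13 (2.99 ± 0.23), collagen Col1a1 (2.52 ± 0.30) and Timp1, an inhibitor of matrix proteases that was at least 2.15-fold higher. Hepatic stellate cell markers had a median difference of 0.42 (adjusted p = 0.0147 and 0.431). Of 11 measured, 7 rose, 1 fell and 3 did not pass (the same over the list alone), with Col14a1 (0.87 ± 0.14) and the superoxide dismutase Sod3 (0.69 ± 0.12) higher. Endothelium markers had a median difference of 0.33 (adjusted p = 0.000366 and 0.223). Of 18 measured, 9 rose, 0 fell and 9 did not pass (11 higher and 0 lower over the list alone), among them Plvap (0.71 ± 0.08), Ednrb (0.55 ± 0.10) and Stab2 of sinusoidal cells (0.52 ± 0.07). Acute phase proteins had a median difference of 0.14 (adjusted p = 0.0202 and 0.374), a call that ended with median scaling (adjusted p = 0.311). Of 18 measured, 7 rose, 1 fell and 10 did not pass (the same over the list alone), with serum amyloid Saa1 (2.48 ± 0.27, other probe 1.18) and orosomucoid Orm2 (2.22 ± 0.10) beside Lcn2.

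Genes of sterol synthesis, fatty acid oxidation and sex-biased liver expression were lower in HFD liver, and genes of drug and glutathione metabolism were higher. Cholesterol synthesis and uptake genes had a median difference of -0.97 (adjusted p = 2.09e-07 and 0.246). Of 15 measured, 0 rose, 13 fell and 2 did not pass (0 higher and 14 lower over the list alone), with the lanosterol demethylase Cyp51 (-1.81 ± 0.29) and the sterol reductase Tm7sf2 (-1.31 ± 0.11) beside Sqle and Fdps. Fatty acid oxidation and ketogenesis genes had a median difference of -0.18 (adjusted p = 0.000937 and 0.223). Of 23 measured, 0 rose, 10 fell and 13 did not pass (1 higher and 11 lower over the list alone), among them the hormone Fgf21 (-1.37 ± 0.22), Hadha of mitochondrial beta-oxidation (-1.02 ± 0.12) and Cpt1a, the carnitine palmitoyltransferase, which was at least 1.91-fold lower. Male-biased liver genes had a median difference of -0.69 (adjusted p = 1.12e-05 and 0.246). Of 18 measured, 0 rose, 9 fell and 9 did not pass (0 higher and 11 lower over the list alone), with Susd4 (-1.55 ± 0.15) and complement C8b (-1.33 ± 0.20) lower beside Elovl3. Female-biased liver genes had a median difference of -0.67 (adjusted p = 0.0273 and 0.246). Of 11 measured, 3 rose, 7 fell and 1 did not pass (3 higher and 8 lower over the list alone), with A1bg at least 2.12-fold lower and Cyp17a1 lower, while Cyp2b9 and Cyp2b13 were higher. Drug-metabolising cytochromes P450 had a median difference of 0.54 (adjusted p = 2.8e-06 and 0.223). Of 20 measured, 12 rose, 1 fell and 7 did not pass (13 higher and 1 lower over the list alone), with Cyp2c55 (1.78 ± 0.16) higher beside the Cyp2b genes. Nrf2 and glutathione genes had a median difference of 0.25 (adjusted p = 0.000615 and 0.223). Of 25 measured, 12 rose, 1 fell and 12 did not pass (the same over the list alone), with the transferases Gstm2 (1.19 ± 0.18), Gstm1 (0.95 ± 0.14) and Gsta4 (0.86 ± 0.13) among them. Citrate cycle and respiratory chain genes had a median difference of -0.07 (adjusted p = 0.0475 and 0.246). Of 32 measured, 1 rose, 3 fell and 28 did not pass (0 higher and 3 lower over the list alone), with fumarase Fh1 (-0.49 ± 0.09) and cytochrome c, Cycs (-0.31 ± 0.07), lower. This last call ended without ND liver 1, 2 or 3, HFD liver 2 or 3, or LU liver 1 or 2 (adjusted p = 0.0517 to 0.0748), with a stricter detection filter (0.0585) and with the replicate number as a block (0.0586).

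The other lists measured in liver did not pass as groups between HFD and ND, though single members did. Triglyceride synthesis and lipid droplet genes had 7 of 19 genes higher, 7 lower and 5 not passing (7 higher and 8 lower over the list alone, adjusted p = 0.9, median -0.15, mean 0.32, test direction lower), with Plin4 (1.57 ± 0.25) higher beside Cidea. Fatty acid synthesis and desaturation had 1 of 17 genes higher, 5 lower and 11 not passing (the same over the list alone, adjusted p = 0.458), with the carboxylase Acacb (-1.86 ± 0.25) lower and the transcription factor Srebf1 (1.30 ± 0.11) higher. Bile acid synthesis and sterol export had 4 of 15 genes higher, 3 lower and 8 not passing (the same over the list alone, adjusted p = 0.343), with the sterol exporters Abcg5 (1.58 ± 0.06) and Abcg8 (1.41 ± 0.10) higher and Cyp7b1 (-1.04 ± 0.25) lower. Lipolysis and fatty acid uptake had 3 of 17 genes higher, 4 lower and 10 not passing (3 higher and 6 lower over the list alone, adjusted p = 0.371, median 0.01, mean 0.04, test direction lower), with lipoprotein lipase Lpl (2.26 ± 0.14) higher. Glucose production and insulin signalling had 4 of 23 genes higher, 7 lower and 12 not passing (the same over the list alone, adjusted p = 0.0917), with the insulin receptor substrate Irs2 (-1.55 ± 0.18) lower. Circadian clock genes had 5 of 13 genes higher, 3 lower and 5 not passing (6 higher and 3 lower over the list alone, adjusted p = 0.166), with Ciart (2.43 ± 0.42, other probes 1.19 and 2.19), Usp2 (1.80 ± 0.31) and Dbp (1.54 ± 0.25) higher. Adipocyte markers had 6 of 12 genes higher, 2 lower and 4 not passing (the same over the list alone, adjusted p = 0.111). Brown and beige adipocyte genes had 1 of 11 genes higher, 4 lower and 6 not passing (1 higher and 5 lower over the list alone, adjusted p = 0.0603, median -0.21, mean 0.09, test direction lower). Endoplasmic reticulum stress genes had 2 of 21 genes higher, 0 lower and 19 not passing (1 higher and 0 lower over the list alone, adjusted p = 0.794). Immediate early and heat shock genes had 5 of 21 genes higher, 3 lower and 13 not passing (7 higher and 3 lower over the list alone, adjusted p = 0.343). T and NK cell markers had 3 of 9 genes higher, 0 lower and 6 not passing (the same over the list alone, adjusted p = 0.15). Neutrophil and mast cell markers had 2 of 6 genes higher, 0 lower and 4 not passing (the same over the list alone, adjusted p = 0.0972). Hepatocyte markers had 0 of 20 genes higher, 1 lower and 19 not passing (the same over the list alone, adjusted p = 0.24). Mesothelium markers had 2 of 5 genes higher, 0 lower and 3 not passing (3 higher and 0 lower over the list alone, adjusted p = 0.0972). Preadipocyte and fibroblast markers had 2 of 10 genes higher, 0 lower and 8 not passing (the same over the list alone, adjusted p = 0.518). Erythrocyte markers had 0 of 6 genes higher, 0 lower and 6 not passing (the same over the list alone, adjusted p = 0.696).

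**Figure D1:**
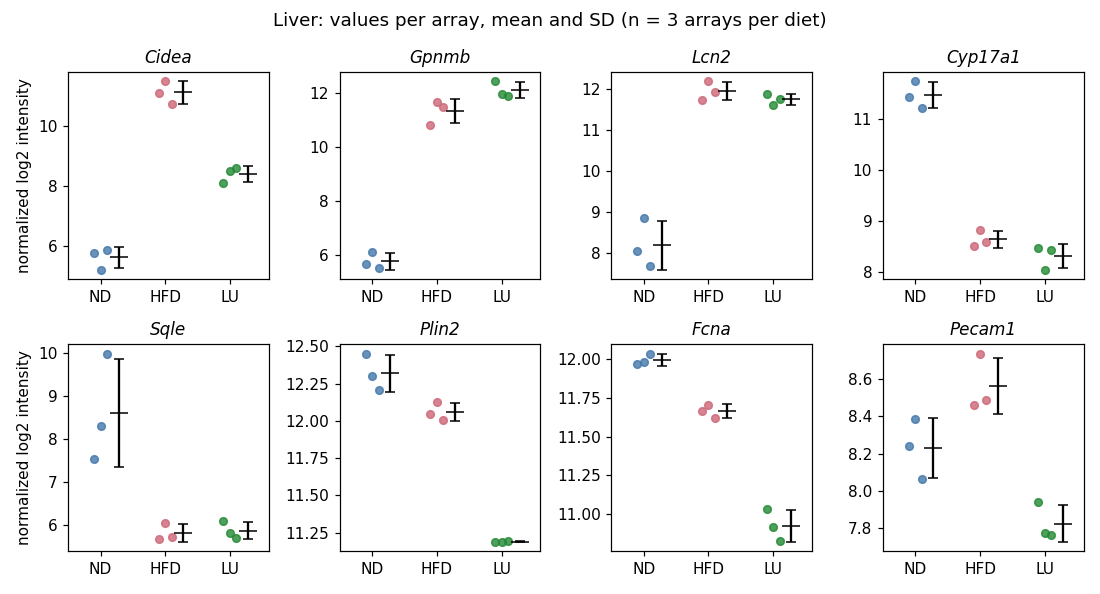
Normalized log2 intensity of 8 genes in liver on each array, by diet on the x-axis, with points for single arrays and black bars for the mean and SD of the 3 arrays of a diet. The mean of Cidea, undetected on ND, was 5.63 on ND, 11.12 on HFD and 8.40 with luteolin, while that of Sqle was 8.60, 5.81 and 5.86.

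The comparison of LU with HFD liver asks what luteolin changed in liver on top of the high-fat diet, the study's question for this organ. Lipid droplet genes, Kupffer cell markers and endothelium markers were lower in LU than in HFD liver. Cidea was 6.59-fold lower (-2.72 ± 0.22, adjusted p = 0.00053), and its LU mean stayed above the ND mean. Irs2, which carries the insulin signal, rose 1.99-fold (0.99 ± 0.18, adjusted p = 0.009). Cd163, a scavenger receptor of macrophages, was not detected on the LU arrays and was at least 1.91-fold lower (-1.43 ± 0.14). The calcium-binding protein gene Cib3 rose most (1.67 ± 0.27, 3.19-fold), and the immune checkpoint gene Cd276 (1.21 ± 0.08), Dclk3 (1.08 ± 0.12), Emp2 (1.03 ± 0.16), Unc13b (0.99 ± 0.15) and Kat14 (0.96 ± 0.11) rose too, while Cyp2g1 was at least 1.82-fold higher. Cyp2b13 (-2.82 ± 0.22), Cyp2b10 (-1.88 ± 0.23) and Chp1 (-1.51 ± 0.17) fell, with the same doubt about which Cyp2b member the probes read. Of the 8 genes with the largest decrease, Cyp2b9, Cyp2b23 and Ugt1a5 lost their calls when any LU or HFD array (Cyp2b9), any of these or ND liver 3 (Cyp2b23), or HFD liver 1 or 2 or LU liver 2 or 3 (Ugt1a5) was left out, with adjusted p up to 0.089, 0.133 and 0.0773. In all, 752 genes rose and 774 fell, of which 5 and 36 did so by more than 2-fold, and median scaling gave 326 higher and 781 lower. The total of 1526 was 875, 970 and 783 without HFD liver 1, 2 and 3, and 832, 949 and 759 without LU liver 1, 2 and 3. In the same order the genes that were higher numbered 394, 456, 317, 362, 411 and 327, and those that were lower 481, 514, 466, 470, 538 and 432.

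Triglyceride synthesis and lipid droplet genes had a median difference of -0.45 (adjusted p = 5.53e-06 and 0.0455), the call that held with an estimated correlation. Of 19 measured, 0 rose, 9 fell and 10 did not pass (1 higher and 10 lower over the list alone), with the droplet coat proteins Plin2 (-0.87 ± 0.07) and Plin5 (-0.69 ± 0.09) and the acyltransferase Gpam (-0.83 ± 0.09) lower beside Cidea. Endothelium markers had a median difference of -0.39 (adjusted p = 3.4e-07 and 0.107). Of 18 measured, 0 rose, 10 fell and 8 did not pass (1 higher and 14 lower over the list alone), among them Adgrl4 (-0.85 ± 0.07), Pecam1 (-0.73 ± 0.11) and the angiopoietin receptor Tek (-0.66 ± 0.08). Kupffer cell markers had a median difference of -0.47 (adjusted p = 0.00108 and 0.353), a call that ended with a stricter detection filter (adjusted p = 0.0815). Of 10 measured, 0 rose, 5 fell and 5 did not pass (0 higher and 6 lower over the list alone), with ficolin Fcna (-0.74 ± 0.07) and the lectin Clec4f (-0.59 ± 0.11, other probe -0.28) lower and Timd4 at least 1.34-fold lower. Fatty acid oxidation and ketogenesis genes had a median difference of -0.11 (adjusted p = 0.0133 and 0.296). Of 23 measured, 0 rose, 6 fell and 17 did not pass (0 higher and 7 lower over the list alone), with Pdk4 (-0.75 ± 0.12) and the thioesterase Acot1 (-0.71 ± 0.11) lower. Drug-metabolising cytochromes P450 had a median difference of -0.17 (adjusted p = 0.0106 and 0.353), a call that ended with the stricter filter (adjusted p = 0.221). Of 20 measured, 1 rose, 6 fell and 13 did not pass (the same over the list alone), with Cyp2c39 (-0.85 ± 0.13) lower beside the Cyp2b genes.

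Sterol, cytokine, macrophage, matrix and acute phase lists, which differed between HFD and ND liver, did not pass between LU and HFD liver. Cholesterol synthesis and uptake had 0 of 15 genes higher, 0 lower and 15 not passing (the same over the list alone, adjusted p = 0.589, median 0.02, mean -0.07, test direction lower), with Hsd17b7 at -0.28 ± 0.09 (adjusted p = 0.065). Cytokines and chemokines had 2 of 20 genes higher, 0 lower and 18 not passing (4 higher and 3 lower over the list alone, adjusted p = 0.976). Acute phase proteins had 0 of 18 genes higher, 0 lower and 18 not passing (the same over the list alone, adjusted p = 0.947). Macrophage markers had 3 of 20 genes higher, 2 lower and 15 not passing (the same over the list alone, adjusted p = 0.976, median 0.03, mean -0.01, test direction higher), where the mannose receptor Mrc1 (-0.56 ± 0.06) fell beside Cd163. Lipid-associated macrophage markers had 2 of 13 genes higher, 0 lower and 11 not passing (3 higher and 0 lower over the list alone, adjusted p = 0.362). Extracellular matrix genes had 1 of 21 genes higher, 2 lower and 18 not passing (the same over the list alone, adjusted p = 0.935, median 0.05, mean 0.01, test direction lower). Glucose production and insulin signalling had 4 of 23 genes higher, 1 lower and 18 not passing (4 higher and 3 lower over the list alone, adjusted p = 0.976, median -0.03, mean 0.03, test direction higher), with Socs2 (0.95 ± 0.18) higher beside Irs2. Hepatic stellate cell markers had 2 of 11 genes higher, 1 lower and 8 not passing (the same over the list alone, adjusted p = 0.947), with the receptor Pdgfrb (0.70 ± 0.10) higher. Hepatocyte markers had 3 of 20 genes higher, 0 lower and 17 not passing (the same over the list alone, adjusted p = 0.38), with albumin Alb (0.69 ± 0.09) higher. Nrf2 and glutathione genes had 2 of 25 genes higher, 1 lower and 22 not passing (1 higher and 1 lower over the list alone, adjusted p = 0.343), with Gstm2 (-1.13 ± 0.18) lower. Endoplasmic reticulum stress genes had 0 of 21 genes higher, 2 lower and 19 not passing (the same over the list alone, adjusted p = 0.343), with Edem1 (-0.91 ± 0.09) lower. Circadian clock genes had 4 of 13 genes higher, 1 lower and 8 not passing (5 higher and 1 lower over the list alone, adjusted p = 0.362), with the repressors Nr1d1 (0.75 ± 0.12) and Nr1d2 (0.59 ± 0.11) higher.

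The comparison of LU with ND liver asks how far liver on the luteolin diet stood from liver on the normal diet. Inflammatory genes were higher and sterol synthesis genes lower in LU than in ND liver. Gpnmb rose (6.32 ± 0.24, other probe 1.33), Lcn2 was 11.7-fold higher (3.55 ± 0.25), and Sdcbp2 at least 5.88-fold higher (other probe 1.05). Cyp17a1 was 8.85-fold lower (-3.15 ± 0.16), Ppp1r3g fell (-3.04 ± 0.58, other probe -1.01), the heat shock gene Hspa1a fell (-3.04 ± 0.46) and Elovl3 fell (-2.97 ± 0.22). Cholesterol synthesis genes had a median difference of -1.07 (adjusted p = 2.56e-06 and 0.37). Of 15 measured, 0 rose, 12 fell and 3 did not pass (0 higher and 14 lower over the list alone). Cytokines and chemokines had a median difference of 0.81 (adjusted p = 2.56e-06 and 0.3). Of 20 measured, 15 rose, 1 fell and 4 did not pass (16 higher and 1 lower over the list alone). Circadian clock genes had a median difference of 0.87 (adjusted p = 0.0329 and 0.37), a call that ended without LU liver 1 (adjusted p = 0.0561). Of 13 measured, 9 rose, 2 fell and 2 did not pass (the same over the list alone). In all, 2116 genes rose and 1557 fell, and 17 of 31 lists passed, 10 higher and 7 lower.

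In epididymal fat the comparison of HFD with ND asks what the high-fat diet changed in adipose tissue. HFD fat held more transcript of genes of macrophages, chemokines and matrix than ND fat, and less of adipocyte and mitochondrial genes. Trem2, the lipid receptor of lipid-associated macrophages, was 18.7-fold higher (4.23 ± 0.19, adjusted p = 8.2e-07), and Mmp12, the macrophage elastase, 21.3-fold higher (4.42 ± 0.17, adjusted p = 6.2e-07). The integrin Itgad was not detected on the 3 ND arrays and was at least 12.2-fold higher (4.33 ± 0.17). Rgs1, a regulator of G protein signalling in leukocytes, was 23.0-fold higher (4.53 ± 0.15). Rbp4, the retinol-binding protein secreted by adipocytes, fell (-1.03 ± 0.09). The tryptophan hydroxylase Tph2 (4.43 ± 0.46), the ubiquitin-like Ubd (3.96 ± 0.20) and serum amyloid Saa3 (3.78 ± 0.17) also rose, and Vsig8 was at least 11.5-fold higher. The acyl-CoA synthetase Acsm3 was 13.1-fold lower (-3.71 ± 0.26, other probes -1.66 and -4.06), and paraoxonase Pon1 at least 5.96-fold lower. Cyp2f2 (-2.76 ± 0.16), Fam13a (-2.55 ± 0.24), Mycl (-2.21 ± 0.30), the carboxylesterase Ces1f (-2.17 ± 0.18), the glutathione transferase Gsta4 (-2.08 ± 0.10) and the red cell anion exchanger Slc4a1 (-2.05 ± 0.46) fell. In all, 2206 genes rose and 2447 fell, of which 436 and 123 did so by more than 2-fold.

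Macrophage, lymphocyte, cytokine and matrix lists rose in HFD fat, while neutrophil and mast cell markers did not pass. Lipid-associated macrophage markers had a median difference of 1.47 (adjusted p = 2.21e-12 and 0.17). Of 18 measured, 17 rose, 0 fell and 1 did not pass (the same over the list alone), with Gpnmb (3.59 ± 0.15) and Clec4d (3.09 ± 0.14) beside Trem2 and Mmp12. Macrophage markers had a median difference of 1.19 (adjusted p = 1.25e-11 and 0.29). Of 21 measured, 19 rose, 1 fell and 1 did not pass (the same over the list alone), including cathepsin S, Ctss (2.30 ± 0.16), Mpeg1 (1.96 ± 0.12) and Adgre1, which encodes F4/80 (1.75 ± 0.10). Cytokines and chemokines had a median difference of 0.92 (adjusted p = 8.1e-08 and 0.17). Of 23 measured, 16 rose, 2 fell and 5 did not pass (17 higher and 2 lower over the list alone), among them the monocyte attractant Ccl2 (2.12 ± 0.09) and Ccl4 (1.56 ± 0.09), and the receptor antagonist Il1rn was at least 8.88-fold higher (other probe 1.44). B and plasma cell markers had a median difference of 1.04 (adjusted p = 0.00517 and 0.29). Of 6 measured, 4 rose, 0 fell and 2 did not pass (the same over the list alone), with Cd72 (2.96 ± 0.14) and Blnk (2.18 ± 0.14) higher. T and NK cell markers had a median difference of 0.30 (adjusted p = 0.00908 and 0.349). Of 13 measured, 6 rose, 1 fell and 6 did not pass (the same over the list alone), with the interleukin 7 receptor Il7r (3.25 ± 0.15, other probes 1.11 and 2.49) and Cd6 (0.97 ± 0.13) higher. Extracellular matrix genes had a median difference of 0.56 (adjusted p = 1.04e-06 and 0.233). Of 28 measured, 20 rose, 1 fell and 7 did not pass (21 higher and 1 lower over the list alone), with Timp1 (2.47 ± 0.19), collagen Col3a1 (1.52 ± 0.11) and Mmp3 (1.36 ± 0.17) higher. Cholesterol synthesis and uptake genes had a median difference of 0.43 (adjusted p = 0.0132 and 0.498). Of 17 measured, 9 rose, 1 fell and 7 did not pass (11 higher and 1 lower over the list alone), among them Dhcr7 (1.13 ± 0.22) and Insig1 (1.08 ± 0.17). Acute phase proteins had a median difference of 0.30 (adjusted p = 0.0252 and 0.323), a call that ended without ND adipose 2 (adjusted p = 0.102), with cyclic loess (0.0849) and with no detection filter (0.0785). Of 14 measured, 7 rose, 2 fell and 5 did not pass (the same over the list alone), with Saa3 and metallothionein Mt2 (0.87 ± 0.15) higher and ceruloplasmin Cp (-1.03 ± 0.08, other probes -0.42, -0.86 and -0.58) lower. Hepatocyte markers had a median difference of 1.28 (adjusted p = 0.0153 and 0.233), a call that ended without ND adipose 2 (adjusted p = 0.121) and with no detection filter (0.575). Of 5 measured, 4 rose, 1 fell and 0 did not pass (the same over the list alone), with the urea cycle enzymes Ass1 (1.94 ± 0.12) and Arg1, at least 2.34-fold higher (other probe 0.67).

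Adipocyte markers and genes of the citrate cycle and respiratory chain were lower in HFD fat, where macrophage markers were higher. Adipocyte markers had a median difference of -0.37 (adjusted p = 0.00323 and 0.349). Of 21 measured, 1 rose, 14 fell and 6 did not pass (the same over the list alone), with Pck1 of glyceroneogenesis (-1.39 ± 0.13), the receptor Acvr1c (-1.20 ± 0.11) and Nnat (-0.76 ± 0.10) lower beside Rbp4. Citrate cycle and respiratory chain genes had a median difference of -0.34 (adjusted p = 1.06e-06 and 0.143). Of 32 measured, 0 rose, 24 fell and 8 did not pass (the same over the list alone), with the complex subunits Ndufs7 (-0.53 ± 0.08) and Uqcrc2 (-0.47 ± 0.06) lower. Glucose production and insulin signalling genes had a median difference of -0.32 (adjusted p = 0.0175 and 0.349). Of 22 measured, 3 rose, 13 fell and 6 did not pass (the same over the list alone), with glycogen phosphorylase Pygl (-1.08 ± 0.10) and the insulin signalling adaptor Grb10 (-0.89 ± 0.09) lower. Mesothelium markers had a median difference of -0.40 (adjusted p = 0.0147 and 0.323). Of 15 measured, 1 rose, 10 fell and 4 did not pass (1 higher and 11 lower over the list alone), among them uroplakin Upk3b (-0.78 ± 0.15) and Gpm6a (-0.67 ± 0.12). Erythrocyte markers had a median difference of -0.52 (adjusted p = 0.0235 and 0.483), a call that ended with a stricter detection filter (adjusted p = 0.107). Of 8 measured, 0 rose, 4 fell and 4 did not pass (0 higher and 6 lower over the list alone), with the haem synthesis enzyme Alas2 (-1.64 ± 0.32) lower beside Slc4a1.

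No other list passed as a group in HFD fat, with single members on both sides. Circadian clock genes had 1 of 14 genes higher, 7 lower and 6 not passing (the same over the list alone, adjusted p = 0.0844), with Nr1d1 (-0.82 ± 0.10) and Per2 (-0.76 ± 0.12) lower. Triglyceride synthesis and lipid droplet genes had 3 of 18 genes higher, 8 lower and 7 not passing (the same over the list alone, adjusted p = 0.299), with Cidea (-1.36 ± 0.18) lower and Plin2 (0.90 ± 0.10) higher. Fatty acid synthesis and desaturation had 1 of 17 genes higher, 5 lower and 11 not passing (1 higher and 4 lower over the list alone, adjusted p = 0.313), with the desaturase Scd2 (1.64 ± 0.38) higher and Acacb (-1.41 ± 0.16) lower. Fatty acid oxidation and ketogenesis had 2 of 19 genes higher, 3 lower and 14 not passing (the same over the list alone, adjusted p = 0.93, median -0.02, mean 0.02, test direction lower), with Cpt1b (1.33 ± 0.08, other probe 0.56) higher. Lipolysis and fatty acid uptake had 2 of 19 genes higher, 6 lower and 11 not passing (the same over the list alone, adjusted p = 0.469), with hormone-sensitive lipase Lipe (-0.58 ± 0.10, other probe -0.25) lower. Bile acid synthesis and sterol export had 3 of 9 genes higher, 4 lower and 2 not passing (the same over the list alone, adjusted p = 0.93, median -0.17, mean 0.12, test direction higher), with Abcg1 (0.75 ± 0.07) higher. Nrf2 and glutathione genes had 6 of 24 genes higher, 10 lower and 8 not passing (7 higher and 10 lower over the list alone, adjusted p = 0.546, median 0.00, mean -0.15, test direction lower), with haem oxygenase Hmox1 (1.18 ± 0.18) higher. Immediate early and heat shock genes had 6 of 22 genes higher, 6 lower and 10 not passing (7 higher and 7 lower over the list alone, adjusted p = 0.586), with Egr2 (2.72 ± 0.15) and Fos (1.64 ± 0.13) higher. Endoplasmic reticulum stress genes had 6 of 21 genes higher, 7 lower and 8 not passing (the same over the list alone, adjusted p = 0.89). Brown and beige adipocyte genes had 6 of 12 genes higher, 3 lower and 3 not passing (the same over the list alone, adjusted p = 0.407). Neutrophil and mast cell markers had 3 of 10 genes higher, 2 lower and 5 not passing (the same over the list alone, adjusted p = 0.469), with S100a8 (1.93 ± 0.30) higher. Endothelium markers had 1 of 18 genes higher, 5 lower and 12 not passing (the same over the list alone, adjusted p = 0.136). Preadipocyte and fibroblast markers had 4 of 17 genes higher, 4 lower and 9 not passing (5 higher and 5 lower over the list alone, adjusted p = 0.475). Skeletal muscle markers had 3 of 6 genes higher, 2 lower and 1 not passing (the same over the list alone, adjusted p = 0.193), with parvalbumin Pvalb (3.59 ± 0.18) higher. Kupffer cell markers had 2 of 9 genes higher, 3 lower and 4 not passing (the same over the list alone, adjusted p = 0.947, median 0.04, mean 0.03, test direction lower). Hepatic stellate cell markers had 4 of 10 genes higher, 0 lower and 6 not passing (the same over the list alone, adjusted p = 0.213). Cholangiocyte markers had 1 of 5 genes higher, 2 lower and 2 not passing (the same over the list alone, adjusted p = 0.838). Male-biased liver genes had 1 of 10 genes higher, 5 lower and 4 not passing (the same over the list alone, adjusted p = 0.108). Female-biased liver genes had 1 of 5 genes higher, 3 lower and 1 not passing (the same over the list alone, adjusted p = 0.15).

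**Figure D2:**
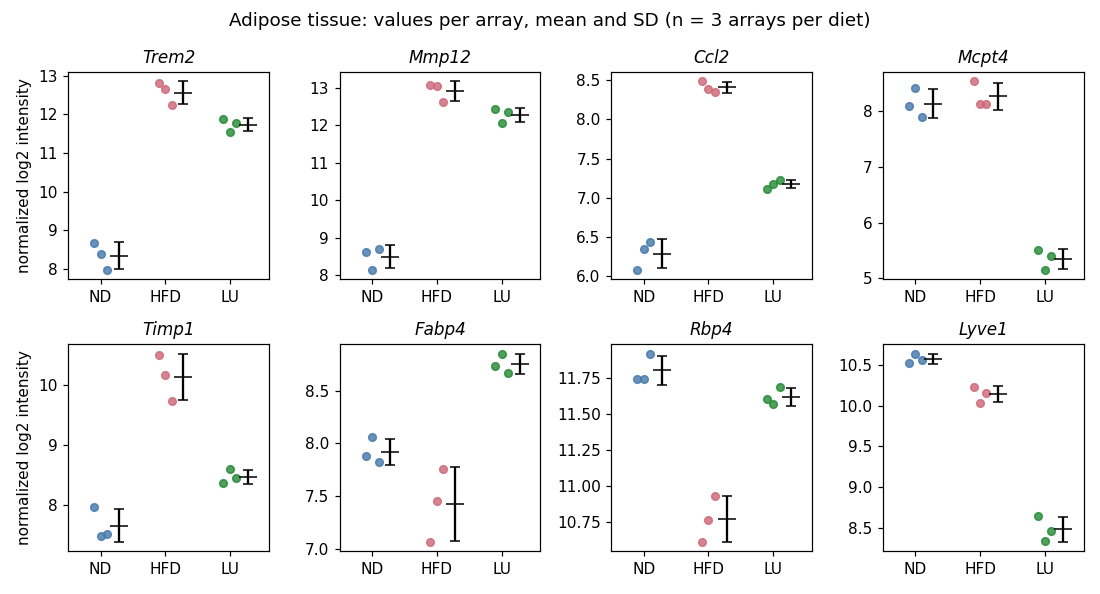
Normalized log2 intensity of 8 genes in epididymal fat on each array, by diet on the x-axis, with points for single arrays and black bars for the mean and SD of 3 arrays. The mean of Trem2 was 8.34 on ND, 12.57 on HFD and 11.73 with luteolin, and that of Mcpt4 8.13, 8.26 and 5.35, the last undetected and at background.

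The comparison of LU with HFD fat asks what luteolin changed in adipose tissue on the high-fat diet. LU fat held less transcript of mast cell proteases, macrophage markers, chemokines and matrix genes than HFD fat, and more of adipocyte and mitochondrial genes. Cpa3, the mast cell carboxypeptidase, was lower (-3.58 ± 0.20, adjusted p = 3.8e-05, other probes -0.95 and -3.85). The chymase Mcpt4 was not detected on the LU arrays and was at least 4.68-fold lower (-2.90 ± 0.16). The chemokine Ccl2 fell (-1.23 ± 0.09, adjusted p = 0.00023), and Fabp4, the fatty acid carrier of adipocytes, rose 2.51-fold (1.33 ± 0.15). Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, was 3.17-fold lower (-1.66 ± 0.09). The mast cell genes Cma1 (-2.58 ± 0.25), Cma2 (-2.69 ± 0.19) and Tpsb2 (-1.81 ± 0.14), the integrin Itgad (-1.87 ± 0.17) and the complement receptor Vsig4 (-1.86 ± 0.15) fell, and the peptide hormone gene Cck was at least 1.89-fold lower. The largest rises were in ND6, a mitochondrially encoded subunit of complex I (1.79 ± 0.16), Cfap65 (1.74 ± 0.19), Rbfox3 (1.51 ± 0.15), Ush1c (1.35 ± 0.25) and Wnk2 (1.33 ± 0.18), with Fbxw15 at least 1.67-fold higher. Of the 8 genes with the largest rise, Ccdc113 lost its call without LU adipose 2 (adjusted p = 0.0538), and Acsm3 without HFD adipose 1 or LU adipose 1 or 2 (adjusted p up to 0.0613). In all, 1672 genes rose and 1587 fell, of which 51 and 79 did so by more than 2-fold, and the total of 3259 was 2137 without LU adipose 2. The genes that rose numbered 1055 without HFD adipose 2, 1041 without LU adipose 1 and 1016 without LU adipose 2.

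Leukocyte and matrix lists fell together in LU fat. Macrophage markers had a median difference of -0.71 (adjusted p = 3.17e-12 and 0.179). Of 21 measured, 0 rose, 20 fell and 1 did not pass (0 higher and 21 lower over the list alone), with complement C1qc (-1.10 ± 0.08) and C1qb (-0.98 ± 0.11), Ms4a7 (-0.92 ± 0.10) and Adgre1 (-0.84 ± 0.10) lower. Lipid-associated macrophage markers had a median difference of -0.58 (adjusted p = 0.000159 and 0.196). Of 18 measured, 1 rose, 11 fell and 6 did not pass (1 higher and 12 lower over the list alone), with Dcstamp (-0.99 ± 0.09) and cathepsin K, Ctsk (-0.85 ± 0.12), lower and the fatty acid receptor Cd36 (0.83 ± 0.10) higher. Kupffer cell markers, which other resident macrophages share, had a median difference of -0.44 (adjusted p = 0.000296 and 0.0742). Of 9 measured, 0 rose, 7 fell and 2 did not pass (1 higher and 7 lower over the list alone), with Folr2 (-1.11 ± 0.11) and Fcna (-0.99 ± 0.16) lower beside Vsig4. Neutrophil and mast cell markers had a median difference of -1.17 (adjusted p = 6.81e-05 and 0.0742). Of 10 measured, 0 rose, 6 fell and 4 did not pass (the same over the list alone), led by the mast cell genes named above. B and plasma cell markers had a median difference of -0.66 (adjusted p = 0.000303 and 0.139). Of 6 measured, 0 rose, 5 fell and 1 did not pass (0 higher and 6 lower over the list alone), with Blnk (-1.03 ± 0.14) and Cd72 (-0.92 ± 0.14) lower. T and NK cell markers had a median difference of -0.47 (adjusted p = 0.000303 and 0.196). Of 13 measured, 1 rose, 9 fell and 3 did not pass (1 higher and 10 lower over the list alone), with Il7r (-1.04 ± 0.15, other probes -0.40 and -1.34) and Cd3g (-0.90 ± 0.12) lower and perforin Prf1 (0.80 ± 0.14) higher. Cytokines and chemokines had a median difference of -0.55 (adjusted p = 1.58e-09 and 0.0788). Of 23 measured, 1 rose, 18 fell and 4 did not pass (1 higher and 20 lower over the list alone), with Ccl8 (-1.11 ± 0.20) and Il1rn (-0.93 ± 0.18) lower beside Ccl2. Extracellular matrix genes had a median difference of -0.43 (adjusted p = 1.5e-08 and 0.127). Of 28 measured, 0 rose, 18 fell and 10 did not pass (0 higher and 21 lower over the list alone), with Mmp3 (-1.66 ± 0.17), Timp1 (-1.66 ± 0.19) and fibronectin Fn1 (-0.92 ± 0.12, other probe -0.50) lower. Preadipocyte and fibroblast markers had a median difference of -0.29 (adjusted p = 5.26e-05 and 0.127). Of 17 measured, 1 rose, 10 fell and 6 did not pass (1 higher and 11 lower over the list alone), with lumican Lum (-1.30 ± 0.16) and Mfap5 (-1.07 ± 0.12) lower. Mesothelium markers had a median difference of -0.35 (adjusted p = 0.00561 and 0.182), a call that ended with a stricter detection filter (adjusted p = 0.0697). Of 15 measured, 2 rose, 7 fell and 6 did not pass (2 higher and 8 lower over the list alone), with Upk1b (-1.08 ± 0.14) and Slpi (-1.02 ± 0.11) lower and keratin Krt18 (0.98 ± 0.21) higher.

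Adipocyte, mitochondrial and glutathione genes rose in LU fat, where macrophage markers fell and endothelium markers did not pass. Adipocyte markers had a median difference of 0.31 (adjusted p = 0.000128 and 0.196). Of 21 measured, 11 rose, 0 fell and 10 did not pass (12 higher and 0 lower over the list alone), with Nnat (1.10 ± 0.10, other probes 0.69 and 0.44), Rbp4 (0.85 ± 0.09) and Pck1 (0.82 ± 0.13) higher beside Fabp4. Citrate cycle and respiratory chain genes had a median difference of 0.22 (adjusted p = 1.56e-05 and 0.0742). Of 32 measured, 16 rose, 0 fell and 16 did not pass (19 higher and 0 lower over the list alone), with Sdhc (0.40 ± 0.06), Ndufv1 (0.37 ± 0.06) and Ndufs7 (0.36 ± 0.08) higher. Nrf2 and glutathione genes had a median difference of 0.19 (adjusted p = 0.00157 and 0.179). Of 24 measured, 11 rose, 1 fell and 12 did not pass (13 higher and 1 lower over the list alone), with Gsta4 (0.89 ± 0.10) and Gstm4 (0.57 ± 0.07) higher. Fatty acid oxidation and ketogenesis genes had a median difference of 0.18 (adjusted p = 0.0294 and 0.196), a call that ended without HFD adipose 1 (adjusted p = 0.0588) and with the authors' values (0.054). Of 19 measured, 5 rose, 0 fell and 14 did not pass (the same over the list alone), with Acads (0.56 ± 0.09, other probe 0.29) and Hadha (0.45 ± 0.08) higher. Endothelium markers had 1 of 18 genes higher, 3 lower and 14 not passing (1 higher and 2 lower over the list alone, adjusted p = 0.707, median 0.00, mean -0.07, test direction lower). Fatty acid synthesis and desaturation had 4 of 17 genes higher, 0 lower and 13 not passing (the same over the list alone, adjusted p = 0.0945), with the transcription factor Mlxipl (0.70 ± 0.09) and Thrsp (0.66 ± 0.13) higher. Brown and beige adipocyte genes had 5 of 12 genes higher, 2 lower and 5 not passing (the same over the list alone, adjusted p = 0.116), with the coactivator Ppargc1a (0.77 ± 0.12) higher. Circadian clock genes had 7 of 14 genes higher, 2 lower and 5 not passing (the same over the list alone, adjusted p = 0.119), with the repressor Nr1d1 (0.92 ± 0.10) and the output gene Dbp (0.69 ± 0.13) higher.

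Another 6 lists passed in LU fat by margins that single arrays decided. Erythrocyte markers had a median difference of -0.46 (adjusted p = 0.0237 and 0.335), lost without HFD adipose 3 (adjusted p = 0.0576). Of 8 measured, 0 rose, 3 fell and 5 did not pass (0 higher and 4 lower over the list alone), with haemoglobin Hba-a1 (-0.93 ± 0.15) lower, a family whose probes can bind each other's transcripts. Triglyceride synthesis and lipid droplet genes had a median difference of 0.19 (adjusted p = 0.0444 and 0.279), lost without HFD adipose 1 or 3 or LU adipose 2 or 3 (0.0548 to 0.0633), with median scaling (0.0527) and with a stricter filter (0.0616). Of 18 measured, 6 rose, 1 fell and 11 did not pass (the same over the list alone), with the acyltransferase Dgat1 (0.56 ± 0.09) higher. Immediate early and heat shock genes had a median difference of -0.14 (adjusted p = 0.0444 and 0.182), lost without HFD adipose 1 or 3 or LU adipose 3 (0.0548 to 0.0967). Of 22 measured, 0 rose, 6 fell and 16 did not pass (the same over the list alone), with Egr2 (-0.83 ± 0.15) and Fos (-0.70 ± 0.13) lower. Endoplasmic reticulum stress genes had a median difference of -0.12 (adjusted p = 0.0498 and 0.196), lost without HFD adipose 1 or 3 or LU adipose 1, 2 or 3 (0.0524 to 0.0776), with no detection filter (0.0994) and with the replicate number as a block (0.0565). Of 21 measured, 1 rose, 6 fell and 14 did not pass (the same over the list alone), with the chaperone genes Calr (-0.83 ± 0.11) and Sdf2l1 (-0.83 ± 0.10) lower. Hepatic stellate cell markers had a median difference of -0.18 (adjusted p = 0.0444 and 0.33), lost without ND adipose 1 or 2, HFD adipose 1 or LU adipose 2 (0.0502 to 0.085). Of 10 measured, 0 rose, 4 fell and 6 did not pass (the same over the list alone), with Col14a1 (-0.87 ± 0.10, other probe -0.51) lower. Male-biased liver genes had a median difference of 0.27 (adjusted p = 0.0429 and 0.179), lost without ND adipose 1 or HFD adipose 3 (0.0539 and 0.0691), with no detection filter (0.356) and with a stricter one (0.105). Of 10 measured, 5 rose, 0 fell and 5 did not pass (6 higher and 1 lower over the list alone), with C8b (0.68 ± 0.08) higher.

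**Figure D3:**
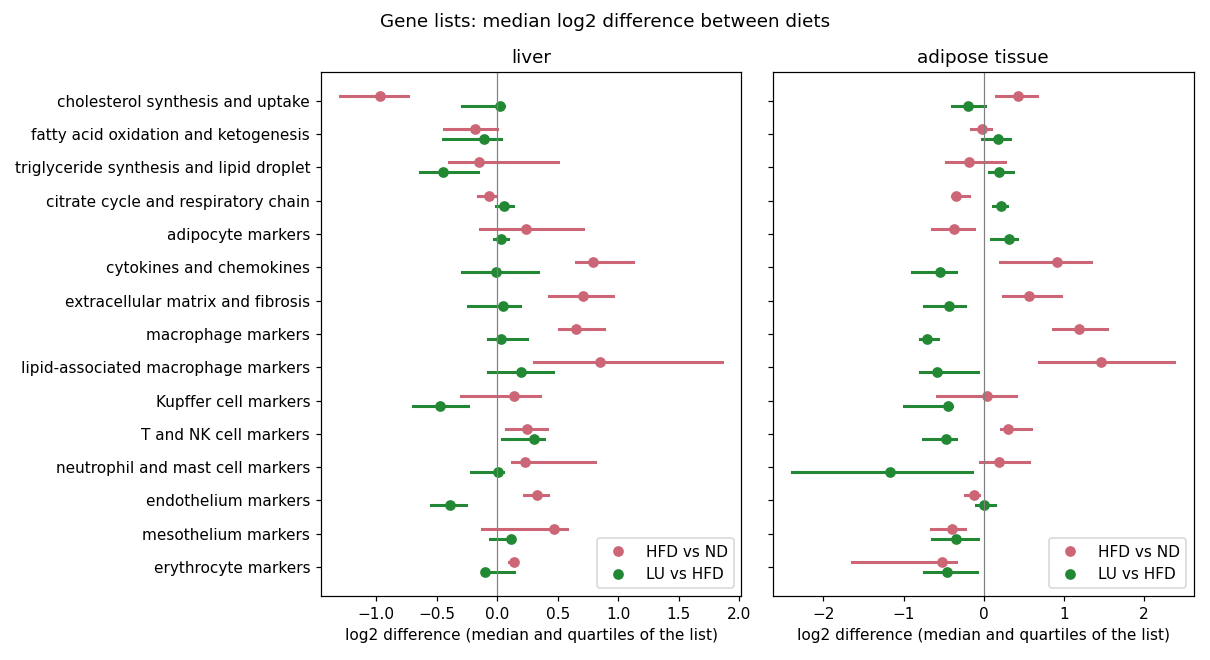
Median and quartiles of the log2 differences within 15 gene lists, as points and bars, for HFD against ND and LU against HFD, in separate panels for liver and fat, with the log2 difference on the x-axis. The macrophage markers lay at 1.19 and -0.71 in fat and the cholesterol synthesis list at -0.97 and 0.02 in liver.

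The comparison of LU with ND fat asks the same of adipose tissue. LU fat held more macrophage and cytokine transcript than ND fat, and less of the mesothelium, erythrocyte, Kupffer cell and the mixed neutrophil and mast cell lists. Tph2 (3.94 ± 0.46), Mmp12 (3.78 ± 0.17) and Trem2 (3.39 ± 0.19) were higher, and Vsig8 was at least 6.81-fold higher. Cpa3 was lower (-2.96 ± 0.20, other probes -0.65 and -3.33) and Mcpt4 at least 4.28-fold lower, and Cyp2f2 (-2.75 ± 0.16) and Pon1 (-2.71 ± 0.23) fell. Lipid-associated macrophage markers had a median difference of 0.98 (adjusted p = 6.36e-12 and 0.118). Of 18 measured, 16 rose, 0 fell and 2 did not pass (the same over the list alone). Macrophage markers had a median difference of 0.53 (adjusted p = 0.000346 and 0.472). Of 21 measured, 13 rose, 3 fell and 5 did not pass (15 higher and 3 lower over the list alone). Cytokines and chemokines had a median difference of 0.29 (adjusted p = 0.0302 and 0.404), a call that ended with no background correction (adjusted p = 0.0525), the authors' values (0.076) and a stricter filter (0.122), and without ND adipose 3 (0.087). Of 23 measured, 12 rose, 4 fell and 7 did not pass (12 higher and 5 lower over the list alone). Citrate cycle and respiratory chain genes had a median difference of -0.08 (adjusted p = 0.023 and 0.198). Of 32 measured, 0 rose, 8 fell and 24 did not pass (0 higher and 7 lower over the list alone). Mesothelium markers had a median difference of -0.81 (adjusted p = 3.68e-05 and 0.118). Of 15 measured, 1 rose, 11 fell and 3 did not pass (2 higher and 11 lower over the list alone). Erythrocyte markers had a median difference of -1.09 (adjusted p = 3.68e-05 and 0.198). Of 8 measured, 0 rose, 8 fell and 0 did not pass (the same over the list alone). Kupffer cell markers had a median difference of -0.46 (adjusted p = 0.000235 and 0.118). Of 9 measured, 0 rose, 8 fell and 1 did not pass (the same over the list alone). Neutrophil and mast cell markers had a median difference of -1.20 (adjusted p = 0.00125 and 0.118). Of 10 measured, 2 rose, 7 fell and 1 did not pass (the same over the list alone). Acute phase (adjusted p = 0.018 and 0.214), brown and beige adipocyte (0.025 and 0.193) and hepatocyte lists (0.025 and 0.193) also passed as higher. Glucose (adjusted p = 0.025 and 0.374), female-biased (0.0308 and 0.198), endothelium (0.048 and 0.731) and preadipocyte lists (0.00163 and 0.198) passed as lower, and the beige, hepatocyte, glucose, female-biased and endothelium calls ended under some alternatives. Adipocyte markers had 4 of 21 genes higher, 4 lower and 13 not passing (the same over the list alone, adjusted p = 0.633). Extracellular matrix genes had 11 of 28 genes higher, 5 lower and 12 not passing (the same over the list alone, adjusted p = 0.389). In all, 1806 genes rose and 1601 fell, and 15 of 33 lists passed, 6 higher and 9 lower, while the total of 3407 genes was 2238 without LU adipose 1. Those that fell numbered 1003 without LU adipose 1 and 1007 without LU adipose 3.

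The luteolin and diet differences were compared in direction, as the study asks whether luteolin opposes the high-fat diet. In fat, 4018 of 4653 genes differing between HFD and ND (86.4%) had the opposite sign between LU and HFD. Both differences use the HFD arrays, so a shift of these, not tested, gives opposite signs. Simulated inert luteolin gave 58.0% on average and 60.6% at most. Of these genes 2051 passed in both with opposite signs (342 raised and 400 lowered expected if independent) and 91 with the same sign. The covariance of both differences over all genes was -0.108 in fat, against -0.00607 in simulated data with no effect. In liver, 1540 of 2704 genes (57.0%) had the opposite sign, against 58.3% on average and 60.3% at most in the simulated data. There 361 passed in both with opposite signs (138 and 93 if independent) and 207 with the same sign. The liver covariance was -0.019, against -0.00691 in simulated data, and the liver count of 1540 was 994 without HFD liver 2. The correlation of both differences was -0.62 in fat and -0.17 in liver. The -0.50 of data simulated without a diet effect is no baseline for these. Trem2 and Ccl2 in fat and Cidea and Irs2 in liver were among the genes that passed in both with opposite signs, while Gpnmb in liver was at 5.56 for HFD against ND and 0.76 for LU against HFD.

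The diet differences were also compared between tissues in 1 model of all 18 arrays, over the 8396 genes measured in both. Between HFD and ND, Cidea was 5.52 in liver and -1.34 in fat (difference 6.86 ± 0.33, adjusted p = 3.7e-09), and Sqle was -2.93 in liver and 0.47 in fat (difference -3.40 ± 0.55). Acsm3 (0.18 in liver, -4.18 in fat), Sdcbp2 (3.98 and -0.36) and Tmem45b (3.43 and -0.18) were on the same side, with liver above fat. Rgs1 (0.46 and 4.65), coagulation factor F7 (-0.26 and 2.91) and Il7r (0.34 and 3.37) had liver below fat. Between LU and HFD, Trem2 was 0.75 in liver and -0.91 in fat (difference 1.65 ± 0.40, adjusted p = 0.012), Timp1 0.42 and -1.72, Cd276 1.26 and -0.66, and the thymidine kinase Tk1 0.53 and -1.12. Cidea was -2.52 in liver and 0.48 in fat (difference -3.00 ± 0.33), the adipocyte gene Adig -1.77 and 0.70, Snhg11 -0.65 and 1.13, and Bex4 -1.11 and 0.58. Cidea, Sdcbp2 and Tmem45b were undetected on all ND liver arrays, F7 on all ND fat arrays and Adig on all LU liver arrays, so the size and order of their differences rest in part on values at background. Within a tissue the bounds were at least 35.1-fold for Cidea, 7.38-fold for Sdcbp2 and 3.64-fold for Tmem45b higher in HFD than ND liver, 5.69-fold higher for F7 in HFD than ND fat, and 1.31-fold lower for Adig in LU than HFD liver. The tissue difference passed for 2861 genes between HFD and ND (1708 with liver above fat, 1153 below) and for 1376 between LU and HFD (731 above, 645 below). Of these, 650 and 397 had opposite signs, which passing itself favours, with arrays that did not overlap in either tissue. With median scaling the counts above and below were 2400 and 673 between HFD and ND, and 395 and 774 between LU and HFD. The 645 below between LU and HFD were 418 and 426 without HFD adipose 1 and 2, and 426 and 403 without LU adipose 1 and 2.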

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

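The tests on the adipocyte share, the lymph node and the splits of both tissues together below were chosen only after the result was seen.

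The effect of a diet differed between tissues, by a test of the difference itself, for 2861 genes between HFD and ND and for 1376 between LU and HFD. Between HFD and ND the liver difference exceeded the fat difference by 6.86 ± 0.33 for Cidea (adjusted p = 3.7e-09), 4.36 ± 0.40 for Acsm3, 4.33 ± 0.23 for Sdcbp2 and 3.60 ± 0.13 for Tmem45b, in log2 units with n = 3 arrays per group. It lay on the other side for Rgs1 (-4.18 ± 0.30), Sqle (-3.40 ± 0.55), F7 (-3.17 ± 0.17) and Il7r (-3.03 ± 0.29). Between LU and HFD the values were 2.14 ± 0.40 for Timp1, 1.92 ± 0.18 for Cd276, 1.65 ± 0.40 for Trem2 and 1.65 ± 0.24 for Tk1. They were -3.00 ± 0.33 for Cidea, -2.48 ± 0.22 for Adig, -1.79 ± 0.13 for Snhg11 and -1.69 ± 0.41 for Bex4. A whole group was undetected for Cidea, Sdcbp2 and Tmem45b (ND liver), F7 (ND fat) and Adig (LU liver), so the size and order of these differences rest in part on background. Of 100 drawn splits of the arrays within both tissues, 2 gave at least 2861 genes for HFD against ND, the real one and 1 that swaps the diets in fat only (4030), and the highest of the rest gave 2202. For LU against HFD 2 of 100 gave at least 1376, the real one and the same swap (2891), and the highest of the rest gave 1022. These draws split liver and fat independently, but the same-numbered ND arrays of both tissues correlated (0.11, 0.16 and 0.18), and the labels do not say whether a number marks 1 mouse. Split together by number, both tissues make only 10 splits, too few for a share under 0.05, where the highest other gave 0 genes for both.

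Within a tissue 3 arrays against 3 make only 10 splits, too few for a share under 0.05. The real split alone (1 of 10) gave 2704, 1526 and 3673 genes in liver for HFD against ND, LU against HFD and LU against ND, and 4653, 3259 and 3407 in fat, where the highest other split gave 0 each time.

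Detected probes without a gene name, which no comparison of the report uses, passed the same threshold in numbers of 595, 449 and 929 of 3176 in liver for HFD against ND, LU against HFD and LU against ND. In fat 1092, 943 and 987 of 4275 passed.

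Arrays of a group correlated at 0.992 or more (LU fat 0.9975 to 0.9976). Repeats of 1 RNA pool would hold genes that vary between animals as steady as other genes. The immediate early, clock and erythrocyte genes had a median residual SD of 0.298 in liver (n = 40), at percentile 100 of 1000 random lists matched on level, whose highest was 0.148. In fat it was 0.16 (n = 44), also at percentile 100 (highest 0.132). The SD pools the diets, so these values argue against pool repeats in all diets at once, not in 1 such as LU fat. Separate pieces or extractions of 1 tissue stay open.

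Macrophage markers in fat rose on the high-fat diet and fell with luteolin. A change in the share of adipocytes alone would move the markers of other cell types alike, and between HFD and ND the mesothelium list had a median of -0.40 (quartiles -0.66 to -0.23, n = 15) beside 1.19 for macrophages. Between LU and HFD the macrophage median was -0.71 (upper quartile -0.57, n = 21) beside 0 for endothelium (lower quartile -0.09), so both values argue against that share as the whole cause. Other lists went with a part for it between LU and HFD, with medians of -0.35 for mesothelium, -0.29 for preadipocyte, -0.47 for T and NK cell, -0.66 for B and plasma cell and -0.46 for erythrocyte markers, and 0.31 for adipocyte markers. Lymph node in the dissected fat as a candidate source would raise lymphocyte genes at least as much, and the T, NK, B and plasma cell markers had a pooled median of 0.38 (n = 19), below the macrophage lower quartile of 0.87, of which Ccl5 and Thy1 also stand in other lists. The B and plasma cell list alone, with a median of 1.04 (quartiles 0.22 to 1.98), went with a lymph node, as did Il7r (8.17 to 11.42 from ND to HFD). The T and NK cell list, at 0.30 (0.21 to 0.59), with Cd3d (7.45 to 7.40) and Cd3e (7.73 to 7.78), argues against a lymph node as the whole source of the rise. For the fall with luteolin a lymph node stays open, since the pooled median was -0.58 (n = 19), between the macrophage median and upper quartile. A change in macrophage number or in their expression, with the diets as the biological explanation, stays open and untested.

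Clock genes differed between diets in liver. Tissues collected at different clock times may explain this, since it predicts the same movement in fat, and between LU and ND the log2 differences of 13 clock genes correlated between tissues at 0.548 (0.291 to 0.732, 1 standard error either side), though the genes are not independent. That explanation stays open for LU against ND, where Dbp was 2.36 in liver and 0.71 in fat, and Per2 1.22 and -0.70. Between HFD and ND the correlation was 0.242 (-0.0689 to 0.511), too uncertain for the clock time and an effect of diet to be told apart.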

How the results depend on the processing

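Cyclic loess and median scaling for the list tests and the opposite-sign counts were tests chosen only after the result was seen. Every total of genes within a tissue or between tissues stayed within 1.5 times its value under the alternatives that kept all arrays. By direction, median scaling went further: 476 lower for 1105 (HFD against ND, liver), 326 higher for 752 (LU against HFD, liver), and for the tissue differences 673 for 1153 and 395 for 731. No gene past the threshold and named in the report changed sign, and of 9277 values of 488 named results 8788 kept their side of the threshold, 468 lost it, 21 gained it and 0 turned. All alternatives were passed by 129 of 134 named calls for HFD against ND in fat, 92 of 104 in liver, 101 of 127 for LU against HFD in fat and 41 of 81 in liver. The lost calls belong to genes of the naming rule not described here, apart from Cyp2b9, Cyp2b23, Ugt1a5, Ccdc113 and Acsm3. Of 85 list calls 57 were kept under all alternatives apart from the other list tests, and 28 were lost under some.

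With 1 array left out, the genes between LU and HFD numbered 759 to 1555 in liver (1526 with all arrays) and 2137 to 3811 in fat (3259). Between LU and ND they numbered 2238 to 3533 in fat (3407), and the liver genes of opposite sign 994 to 1544 (1540). These fit fewer samples, which in part lowers the counts. With the replicate number as a block the counts were 2344, 1122 and 3387 in liver and 4366, 2944 and 3098 in fat. For the tissue differences they were 2802 and 1252. Pairing was not assumed but stays open across tissues: 7 of 9 arrays matched their own number best. There 3 of 9 pairs, all of ND, correlated over 0.1 (-0.11 to 0.18). Across diets 1 of 9 did in liver and 0 of 9 in fat. The files give no slide, so no slide block was run.

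The test used for lists mattered most for their number. With an estimated correlation 0, 1 and 0 lists passed in liver for HFD against ND, LU against HFD and LU against ND, and 0, 0 and 0 in fat. With fry 23 lists passed in liver for HFD against ND (14 with camera), 8 for LU against HFD (5) and 24 in fat for HFD against ND (14). With the stricter detection filter 3 lists passed in liver for LU against HFD, where fewer genes were tested.

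The direction of the camera test turned in 90 cases among 31 list results, none past the threshold before or after, and the cause was not tested. The values below are mean log2 differences. With the authors' values they were 0.01 for cytokines (LU against HFD, liver), 0.08 and 0.12 for cholangiocyte markers (LU against HFD and ND, fat), 0.27 for triglyceride genes (HFD against ND, liver) and 0.02 (LU against ND, fat). With cyclic loess they were -0.01 for adipocyte markers and -0.03 for cytokines (LU against HFD, liver), 0.16 for bile acid genes (HFD against ND, fat), 0.06 for cholangiocyte markers (LU against HFD, fat), 0.09 for hepatocyte markers (LU against ND, liver), and 0.09 for fatty acid synthesis and 0.02 for triglyceride genes (LU against ND, fat). With median scaling they were -0.05 for adipocyte markers and -0.05 for cytokines (LU against HFD, liver), 0.21 for endoplasmic reticulum stress, 0.09 for Kupffer and 0.10 for erythrocyte markers (HFD against ND, liver), and 0.09 for fatty acid synthesis and 0.03 for triglyceride genes (LU against ND, fat). With no background correction they were 0.08 and 0.12 for cholangiocyte markers (LU against HFD and ND, fat) and 0.12 for erythrocyte markers (LU against ND, liver). With no detection filter they were 0.06 for endoplasmic reticulum stress (HFD against ND, liver), 0.04 for matrix genes and 0.02 for stellate markers (LU against HFD, liver), 0.06 for hepatocyte markers (LU against ND, liver), 0.03 for Kupffer markers (HFD against ND, fat), 0.07 and 0.01 for cholangiocyte markers (LU against HFD and ND, fat) and 0.11 for B and plasma cell markers (LU against ND, fat). With the stricter filter they were 0.00 for adipocyte, 0.03 for cytokine, 0.00 for stellate and 0.01 for macrophage lists (LU against HFD, liver) and 0.07 for Kupffer markers (HFD against ND, fat). With the replicate block they were 0.07 for T and NK cell markers (LU against ND, fat) and 0.15 for erythrocyte markers (LU against ND, liver).

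With 1 array left out, the means of lists whose direction turned ranged as follows. In liver between HFD and ND they ranged over -0.15 to 0.24 for endoplasmic reticulum stress, -0.20 to 0.19 for fatty acid synthesis, 0.31 to 0.33 for triglyceride genes and -0.03 to 0.04 for Kupffer markers. In liver between LU and HFD the ranges were -0.01 to 0.03 for adipocyte, 0.01 to 0.09 for acute phase, -0.11 to 0.06 for macrophage, 0.01 to 0.14 for stellate and 0.07 to 0.11 for mesothelium lists, -0.07 to 0.05 for cytokines, -0.11 to 0.14 for matrix, -0.01 to 0.06 for glucose, 0.01 to 0.36 for male-biased and -0.25 to 0.27 for erythrocyte lists. Erythrocyte markers between LU and ND liver ranged over -0.17 to 0.35. In fat between HFD and ND the ranges were 0.08 to 0.18 for bile acid genes, 0.02 to 0.08 for endoplasmic reticulum stress, -0.27 to 0.05 for cholangiocyte markers and 0.00 to 0.05 for fatty acid oxidation. In fat between LU and HFD they were 0.03 to 0.18 for cholangiocyte, -0.03 to 0.05 for bile acid, -0.08 to 0.05 for female-biased and -0.12 to -0.02 for endothelium lists. In fat between LU and ND they were -0.03 to 0.09 for triglyceride, 0.01 to 0.12 for T and NK cell, -0.24 to 0.19 for cholangiocyte and -0.06 to 0.23 for fatty acid synthesis lists. Signal over background limits dim genes, and those undetected in a whole group have only a lower bound of their fold.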

Other observations

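This part gives values only, chosen after they were seen, and no tests. In fat the mean of Cpa3 was 8.90 on ND, 9.53 on HFD and 5.94 with luteolin (detected on 1 of 3 arrays), with SDs of 0.36, 0.34 and 0.16 over 3 arrays. Lyve1 had means of 10.58, 10.14 and 8.48 in fat. In liver the scavenger receptor Cd163 had means of 7.45, 6.78 and 5.34, the last undetected.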
